A study of Mus musculus with 8 samples.

How the data were processed

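RNA was measured in the livers of 4 mice injected with an adeno-associated virus carrying mouse Nudt7 and 4 injected with one carrying GFP. Per the labels' protocols, 8-week-old C57BL/6J mice received 2.5e+11 viral particles in 150 µl by tail vein, livers were taken 3 to 4 weeks later (at 11 to 12 weeks of age) from mice fasted for 24 h, flash frozen, and extracted with Trizol. Per the labels, 500 ng of RNA went into a stranded mRNA kit from KAPA Biosystems with 9 cycles of PCR, and the libraries were sequenced on an Illumina HiSeq1500. The labels give no sex, batch or pairing of the animals. The Y-linked genes Ddx3y, Eif2s3y and Kdm5d were detected in all 8 libraries.

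Per the submitters' processing notes, the authors used FastQC, Salmon and DESeq2 with genome build GRCm38. The Salmon version, its index and its options are not given in the sources used here, nor whether the index held the vector sequence. The deposited files hold, per the file headers, estimated counts per transcript (Salmon's expected number of reads, not normalized), TPM per transcript and the EffectiveLength of each transcript in bases. The authors' TPM values added up to 1e+06 in each library. Each library had a file of its own, with 109282 transcripts.

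Transcripts were given gene names and positions by their Ensembl identifiers from the GENCODE M21 annotation of GRCm38. Of the 109282 transcripts, 107987 (98.8%) were named, 96.0% with the same version number, and the 1295 that were not named held 0.552% to 1.06% of the reads of a library and were left out. Estimated counts were summed per gene (34547 genes) and rounded to whole numbers. Depth ran from 11187806 to 23640734 estimated reads per library. A gene listed at 0 in a group was given a floor of 3 counts over the group. The floor covers counting error only, and reads made by PCR without molecular identifiers are not independent molecules. The intervals of fold changes come from the quasi-likelihood fit and include variation between livers.

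The main test was edgeR's quasi-likelihood test with robust estimation, TMM scaling and the filterByExpr filter by group, which left 13678 genes. It was two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. CPM values use TMM-scaled library sizes. The common biological coefficient of variation was 0.196 and the median total degrees of freedom 11.5. The 2 groups were compared with no covariate.

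There were 31 gene lists, 11 on metabolism and the clock and 20 on other responses and cell types, with Nudt7 left out of every list. They were written, like the main tests, most alternatives and the rule for which genes to name, before the data were examined; tests and alternatives added later are named as such. The 30 lists with at least 3 tested members were tested with limma's camera on voom log2 CPM with a preset correlation of 0.01 between genes, two-sided, adjusted over the 30 lists. Camera with an estimated correlation and the rotation test fry were run beside it. Member calls were counted over all genes tested and adjusted over the list alone. The neutrophil list had 2 tested members and was not tested; the other lists were CoA synthesis and breakdown, peroxisomal fatty acid oxidation, peroxisome biogenesis, mitochondrial fatty acid oxidation and ketogenesis, PPAR alpha targets, bile acid synthesis, bile acid transport, cholesterol synthesis, fatty acid and triglyceride synthesis, gluconeogenesis, circadian clock, and those given under the other observations.

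Genes were named by a rule. It took Nudt7, up to 10 called genes in each direction with a mean of at least 1 CPM and groups that did not overlap (clone and predicted names left out), up to 4 members of each list with the smallest adjusted p, and a set of metabolic and clock genes reported whatever their result. The gene 4931406C07Rik falls outside the rule by its name and was added after its values were seen, to complete the count of genes that rose. The glucocorticoid-responsive genes Ddit4, Zbtb16, Hif3a and Tgm2 were also named after their values were seen, from a list of 20 genes written before its values were examined.

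The procedure was tested on simulated data, in 5 simulations with 200 changed genes each (13454 to 13479 genes tested). It recovered 15.6% of genes changed 1.5-fold, 66.0% at 2-fold, 92.0% at 4-fold and 94.4% at 8-fold, and 7.43% of its calls were false. More genes passed there than in the real data, which loosens the adjusted threshold, so these recovered shares may be too high for the real libraries. A list shifted by 0.4 log2 units was called in 5 of 5 simulations, with 3 calls of other lists in all. Genes were simulated as independent of each other, so these calls do not give the error rate of camera in the real libraries. There, camera with the preset correlation called a median of 5.5 lists when each side of the split held 2 livers of each group. With a trend in transcript length put into 1 library, true calls numbered 660 before and 704 after the trend was removed.

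The alternatives were DESeq2 size factors, upper-quartile scaling, library size only, Nudt7 left out of the library sizes, no filter, a filter of 1 CPM in 4 samples, DESeq2, limma-voom with and without sample weights, the quasi-likelihood fit without robust estimation, length-scaled TPM, protein-coding genes only, a threshold of 0.1, an added minimum of 1.5-fold, and each library left out in turn. Removal of each library's trend with transcript length, summing of the Apol7 genes, an estimated correlation with the length trend removed or with Nudt7 replicate 3 left out, and the gluconeogenesis list without periportal markers, were added after the data had been seen. A result counts as reversed only where a value called in the main or the alternative fit changes sign; 15 of 1678 gene values and 25 list values changed sign without a call. All 35 splits of the 8 libraries into 4 and 4 were fitted in the same way. No data of another series were used.

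The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.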

Results

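Liver mRNA was sequenced from 8 C57BL/6J mice, 4 that had received an adeno-associated virus (AAV, a gene delivery vector that reaches the liver after tail-vein injection) carrying mouse Nudt7 and 4 that had received the same virus carrying GFP, a fluorescent protein used as the control. Mice were injected at 8 weeks of age, and livers were taken 3 to 4 weeks later after a 24 h fast. The comparison addressed how overexpression of Nudt7, a peroxisomal hydrolase that breaks down coenzyme A and acyl-CoAs, changed the transcriptome of the fasted liver. The Nudt7 libraries held 12450325, 11187806, 14126361 and 15487092 estimated reads in replicates 1 to 4, and the GFP libraries held 14321869, 13394024, 11466892 and 23640734. Between 18362 and 19167 genes were detected per library, and 13678 genes had enough reads to be tested.

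Nudt7, on chromosome 8 (114133557 to 114154739, plus strand, GRCm38), was 27.7-fold higher in the livers that received it. Its level was 2006 ± 1050 CPM (read counts normalised to 1e+06 per library) in Nudt7 livers and 72.3 ± 8.26 CPM in GFP livers (SD, n = 4 each). The individual Nudt7 livers reached 1301, 1599, 3569 and 1555 CPM, against 60.7 to 79.9 CPM in the GFP livers, so that every Nudt7 liver lay above every GFP liver. The log2 fold change was 4.79 (SE 0.33, 95% confidence interval 4.07 to 5.51, edgeR quasi-likelihood adjusted p = 0.000122). In Nudt7 livers, most of the Nudt7 reads were assigned to a pair of short transcripts. ENSMUST00000147605.7, 966 bases long, stood at 1812 ± 657 TPM (transcript abundance normalised for length and library size) in Nudt7 livers and 35.1 ± 6.57 TPM in GFP livers (SD, n = 4 each). ENSMUST00000066514.12, 935 bases long, stood at 1061 ± 343 and 26.9 ± 5.12 TPM. The long transcript ENSMUST00000073521.11, 3543 bases, was at 17.8 ± 1.86 and 8.28 ± 1.03 TPM. The files do not separate reads of the vector from reads of the mouse gene.

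Beside Nudt7, 5 genes rose in Nudt7 livers. Car3, which encodes a cytosolic carbonic anhydrase, went from 8.68 ± 4.67 to 52.6 ± 20.3 CPM (SD, n = 4 each; log2 fold change 2.62, SE 0.39, adjusted p = 0.0423). Cd36, the fatty acid uptake receptor, went from 30.6 ± 4.15 to 68.8 ± 15.8 CPM (1.17, SE 0.18, adjusted p = 0.0423). Clstn3, which encodes calsyntenin-3, went from 15.3 ± 2.91 to 38.5 ± 5.92 CPM (1.33, SE 0.16, adjusted p = 0.0207), and Tlr12, an innate immune receptor gene, from 7.82 ± 1.38 to 20.7 ± 4.63 CPM (1.41, SE 0.19, adjusted p = 0.0336). The gene 4931406C07Rik rose by 0.77 on the log2 scale (SE 0.12, adjusted p = 0.0476). Cd36 lies on chromosome 5 (17781690 to 17888801), Car3 on chromosome 3 (14863512 to 14872523) and Clstn3 on chromosome 6 (124430759 to 124464794). Car3 was also on the list of adipocyte and pancreas markers, whose other tested members, Plin1 and Amy2a5, had log2 fold changes of 0.02 (SE 0.32) and −0.09 (SE 0.47). The adjusted p of Car3 was 0.174 with no filter on low counts and 0.0662 when the trend with transcript length described for the libraries was removed.

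Igfbp1, the gene of a secreted insulin-like growth factor binding protein that the liver makes in fasting, fell from 1079 ± 401 CPM in GFP livers to 267 ± 74.97 CPM in Nudt7 livers (SD, n = 4 each; log2 fold change −2.02, SE 0.29, adjusted p = 0.0400). Slc25a51, the gene of the mitochondrial NAD carrier, fell from 283 ± 40.4 to 132 ± 21.1 CPM (−1.10, SE 0.15, adjusted p = 0.0336). Fkbp5, which encodes a co-chaperone of the glucocorticoid receptor and is itself induced by glucocorticoids, fell from 293 ± 45.7 to 136 ± 29.8 CPM (−1.11, SE 0.18, adjusted p = 0.0476). Adra2a, an adrenergic receptor gene, went from 11.6 ± 6.27 to 1.18 ± 0.8288 CPM (−3.31, SE 0.48, adjusted p = 0.0406), and Itga2, an integrin gene, from 26.7 ± 7.61 to 7.07 ± 2.98 CPM (−1.93, SE 0.29, adjusted p = 0.0406). Myom1 (log2 fold change −1.77, SE 0.25), Olfr713 (−2.26, SE 0.36), Tbc1d8 (−1.09, SE 0.17) and Rasgef1b (−0.72, SE 0.12) also fell, with adjusted p values of 0.0336 for Myom1 and 0.0476 for the other 3. Igfbp1 lies on chromosome 11 (7197782 to 7202546), Slc25a51 on chromosome 4 (45395923 to 45408766) and Fkbp5 on chromosome 17 (28399094 to 28517527).

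Apol7e, an apolipoprotein L gene on chromosome 15 (77698857 to 77719285), was listed at 0 in all 4 Nudt7 livers and at 4.58 ± 1.35 CPM in the 4 GFP livers. It was at least 78.7-fold lower against a floor of 3 counts over the group, or 0.0581 CPM (adjusted p = 0.00301). The value is uncertain, because Apol7e shares 84.2% of its sequence words of 31 bases with other Apol7 genes, and sums over these genes did not pass the test. Apol7b and Apol7e, the copies that share most words, summed to a log2 fold change of −0.32 (SE 0.20, adjusted p = 0.685), and Apol7a, Apol7b, Apol7c and Apol7e, most of whose reads were of Apol7a, to 0.62 (SE 0.20, adjusted p = 0.4003). Apol7d, of which no transcript was listed in the files, was not part of the sums. The floor covers counting error only, whereas the intervals of fold changes include variation between livers.

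In all, 6 genes rose and 10 fell in Nudt7 livers at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg over 13678 genes), and for each of the 16 the 4 livers of one group lay above the 4 of the other. Before adjustment, 1132 genes had an unadjusted p under 0.05, 581 with positive and 551 with negative fold changes, where 683.9 were expected if no gene changed. The groups did not overlap for 786 genes, or 5.75% of those tested, where chance gives 2.86%. Only Nudt7 and Apol7e passed in all 8 fits that each left out 1 library, and the other 14 genes passed in 0 (Fkbp5) to 6 (Clstn3) of them, Igfbp1 in 1. In 13 other alternatives 6 of the 16 genes passed in each; with no filter on low counts the adjusted p was 0.174 for Car3, 0.132 for Adra2a and 0.0528 for Itga2. The genes that rose numbered 1 without Nudt7 replicate 1 or GFP replicate 4, 2 without GFP replicate 2 and 3 without GFP replicate 1. The genes that fell numbered 1 without Nudt7 replicate 1 or 4 or GFP replicate 2 or 4, 2 without GFP replicate 1, and 5 without Nudt7 replicate 2 or 3. DESeq2 called 89 genes higher and 64 lower, among them all 16.

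**Figure D1:**
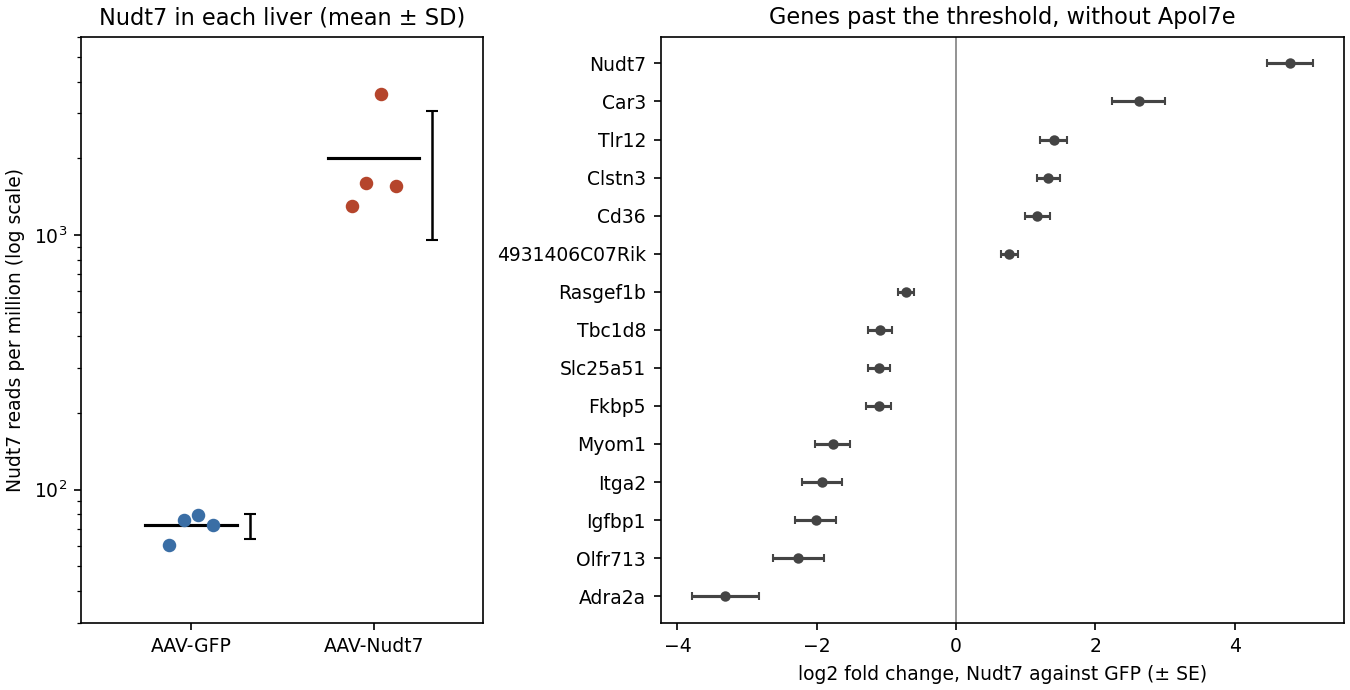
Left, Nudt7 CPM (log scale) in each liver, with the mean (line) and SD (bar beside it) of the 4 livers per group; the Nudt7 livers sit between 1301 and 3569 and the GFP livers between 60.7 and 79.9. Right, log2 fold change with its SE for 15 of the 16 genes past the threshold, Apol7e being left out because it is listed at 0 in every Nudt7 liver.

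One library stood apart from the rest. Nudt7 replicate 3 was at 63.1 on the first principal component, which held 36.3% of the variance, and the other 7 libraries were between −19.9 and 2.83. In that library, genes with short transcripts (the lowest of 3 equal length classes) lay 0.42 log2 units above the other 3 Nudt7 libraries (median), and genes with long transcripts lay at −0.35. Between the groups, the median log2 fold change was 0.11 for the short class and −0.08 for the long class. Nudt7 replicate 3 also held 1813 CPM of red blood cell transcripts, against 303 to 642 CPM in the other 7. Mitochondrially encoded transcripts took 8.41% ± 2.27 of reads in Nudt7 livers and 8.02% ± 1.29 in GFP livers (SD, n = 4 each), and Alb, the most abundant gene, took 4.62% ± 0.706 and 5.10% ± 0.525.

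**Figure D2:**
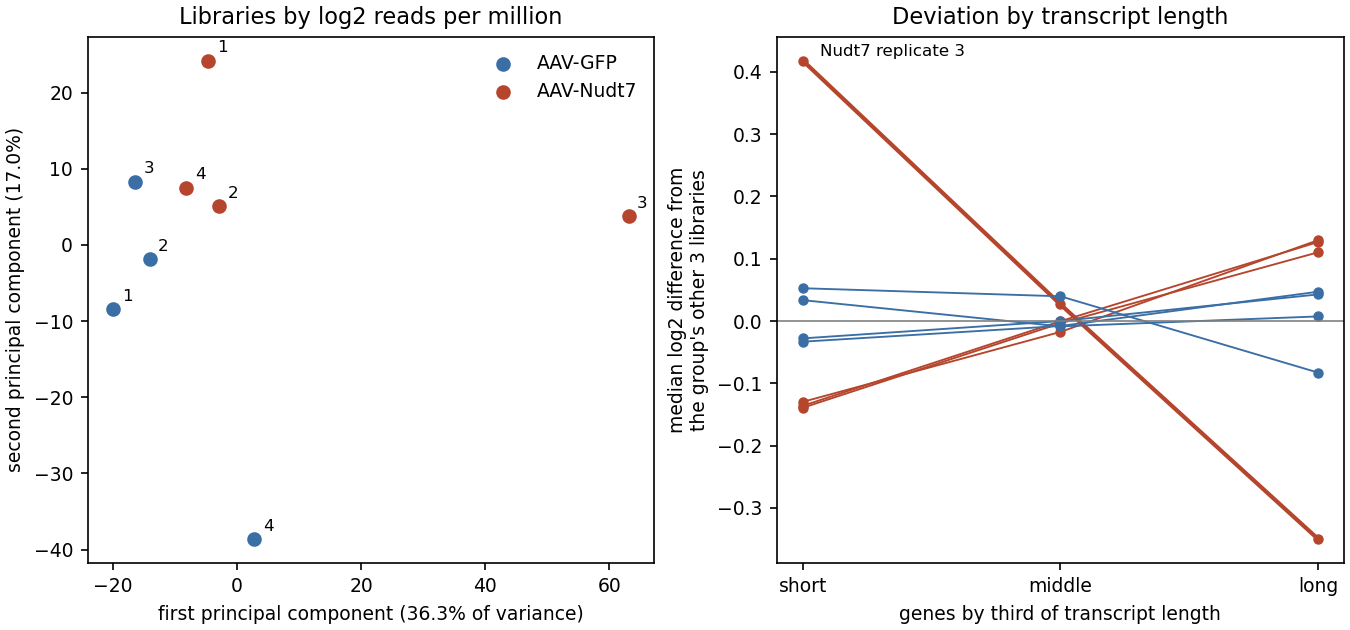
Left, the 8 libraries on the first and second principal components of log2 CPM, numbered by replicate, with Nudt7 replicate 3 at 63.1. Right, the median log2 difference of each library from the other 3 of its group for genes of short, middle and long transcripts; Nudt7 replicate 3 runs from 0.42 to −0.35.

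Genes of coenzyme A synthesis and breakdown, the pathway in which Nudt7 acts, had small fold changes. Of 19 tested members other than Nudt7, 14 had positive fold changes and the median was 0.12 log2 units. Slc25a17, a peroxisomal cofactor carrier gene, was at 0.34 (SE 0.14, adjusted p = 0.561), Dcakd at 0.28 (SE 0.11, adjusted p = 0.532), and Pank1, a pantothenate kinase gene of the first step of synthesis, at 0.16 (SE 0.12, adjusted p = 0.722). Nudt19, the gene of another peroxisomal CoA hydrolase, was at 0.23 (SE 0.17, 95% interval −0.14 to 0.60, adjusted p = 0.714). In edgeR 0 members passed over all genes tested and 0 adjusted over the list alone, while 2 had an unadjusted p under 0.05; DESeq2 and limma-voom each called 0. The list did not pass (camera adjusted p = 0.0866, and adjusted p = 0.341 with an estimated correlation), and it passed at adjusted p = 0.0350 without GFP replicate 4.

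Genes of peroxisomal fatty acid oxidation were higher as a group in Nudt7 livers. Of 28 tested members, 23 had positive fold changes, with a median of 0.23 log2 units, and 3 rose when adjusted over the list alone. These were Acaa1b, a peroxisomal thiolase gene (1.03, SE 0.22, 2415 ± 674 against 1183 ± 224 CPM), Abcd3, which encodes a transporter of acyl-CoAs into peroxisomes (0.55, SE 0.14, 985 ± 89.6 against 674 ± 72.3 CPM), and Crot, the carnitine octanoyltransferase gene (0.56, SE 0.15, 711 ± 129 against 481 ± 43.5 CPM; SD, n = 4 each). Over all genes tested by edgeR 0 members passed, with adjusted p values of 0.126, 0.218 and 0.277 for these 3, while 10 had an unadjusted p under 0.05; DESeq2 called 3, limma-voom 0 and limma-voom with sample weights 3. Ehhadh, the bifunctional enzyme gene, was at 0.92 (SE 0.30, adjusted p = 0.429). Camera gave the list an adjusted p = 4.00e-05 with a preset correlation and an adjusted p = 0.142 with an estimated correlation. Peroxisome biogenesis genes did not pass (21 tested, median 0.13, adjusted p = 0.0866, and adjusted p = 0.649 with an estimated correlation), with Pex6 at −0.36 (SE 0.11, adjusted p = 0.397) and Pex11a at 0.38 (SE 0.17, adjusted p = 0.600). Of these genes 0 passed in edgeR over all genes or adjusted over the list alone and 1 had an unadjusted p under 0.05, and DESeq2 and limma-voom each called 0; the list passed without Nudt7 replicate 1 (0.0331), Nudt7 replicate 4 (0.0175) or GFP replicate 4 (0.0150).

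Mitochondrial fatty acid oxidation and ketogenesis genes were also higher as a group, by small amounts. Of 25 tested members, 23 had positive fold changes, with a median of 0.27 log2 units. Acsl1, which encodes a long-chain acyl-CoA synthetase, was at 0.47 (SE 0.14, adjusted p = 0.351), Eci1 at 0.46 (SE 0.16, adjusted p = 0.470) and Hadh at 0.43 (SE 0.15, adjusted p = 0.464). Cpt1a, the gene of the rate-limiting enzyme of import, was at −0.18 (SE 0.14, adjusted p = 0.725). In edgeR 0 members passed over all genes and 0 adjusted over the list alone, and 6 had an unadjusted p under 0.05; DESeq2 and limma-voom with sample weights each called 1 and limma-voom 0. Camera gave the list an adjusted p = 1.30e-06, and an adjusted p = 0.2999 with an estimated correlation.

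Targets of PPAR alpha, the nuclear receptor that drives fat oxidation genes in fasting, were higher as a group, with 24 of 29 tested members positive and a median of 0.26 log2 units. In edgeR Cd36 alone rose, both over all genes tested and adjusted over the list alone, and 6 members had an unadjusted p under 0.05; DESeq2 called 1, limma-voom 0 and limma-voom with sample weights 2. Fabp1, a fatty acid binding protein gene, was at 0.51 (SE 0.17, adjusted p = 0.425), whereas Pdk4 was at −0.41 (SE 0.43, adjusted p = 0.796) and Fgf21, a hormone gene induced by fasting, at −0.61 (SE 0.30, adjusted p = 0.630). Camera gave the list an adjusted p = 1.11e-05, and an adjusted p = 0.331 with an estimated correlation. Members such as Ehhadh and Cpt1a stood on this list and on those of fat oxidation, so the lists are not independent.

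Bile acid synthesis and conjugation genes were higher as a group in Nudt7 livers, with 14 of 19 tested members positive and a median of 0.20 log2 units. The list shared Acox2, Hsd17b4, Scp2, Abcd3, Acot8, Amacr and Slc27a2 with peroxisomal fatty acid oxidation, so these lists are not independent. Adjusted over the list alone, Abcd3 rose and Cyp39a1, an oxysterol hydroxylase gene, fell (−0.85, SE 0.18, 84.2 ± 3.31 against 151 ± 41.5 CPM; SD, n = 4 each). Over all genes tested by edgeR 0 members passed (Cyp39a1 adjusted p = 0.126) and 5 had an unadjusted p under 0.05; DESeq2 called 1 higher and 1 lower, limma-voom 0, and limma-voom with sample weights 1 higher. Akr1c6 was at 1.24 (SE 0.44, adjusted p = 0.477). Cyp7a1, the rate-limiting enzyme gene, was at 0.36 (SE 0.32, adjusted p = 0.759), Cyp8b1 at 0.07 (SE 0.17, adjusted p = 0.925) and Cyp27a1 at −0.18 (SE 0.20, adjusted p = 0.805). Camera gave the list an adjusted p = 0.0202 and an adjusted p = 0.456 with an estimated correlation, and the call rested on Nudt7 replicate 3, without which the adjusted p was 0.238. Bile acid transport and sensing genes did not pass (18 tested, median −0.05, adjusted p = 0.723, and adjusted p = 0.849 with an estimated correlation). Among them Abcc3 was at 0.50 (SE 0.14, adjusted p = 0.325) and Hnf4a at −0.43 (SE 0.14, adjusted p = 0.422), and in edgeR 0 passed over all genes or adjusted over the list alone, 2 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0.

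Cholesterol synthesis and uptake genes were higher as a group, with 21 of 25 tested members positive and a median of 0.22 log2 units. Mvk, the mevalonate kinase gene, was at 0.92 (SE 0.25, adjusted p = 0.296), Pmvk at 0.54 (SE 0.19, adjusted p = 0.470) and Hmgcs1 at 0.35 (SE 0.13, adjusted p = 0.525). In edgeR 0 members passed over all genes and 0 adjusted over the list alone, and 5 had an unadjusted p under 0.05; DESeq2 and limma-voom each called 0. Camera gave the list an adjusted p = 0.00163, and an adjusted p = 0.142 with an estimated correlation.

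Fatty acid and triglyceride synthesis genes moved in both directions. Adjusted over the list alone, 3 of 24 tested members rose and 1 fell. Scd1, the stearoyl-CoA desaturase gene, went from 755 ± 62.3 to 1663 ± 657 CPM (1.14, SE 0.23), Srebf1, the gene of the lipogenic transcription factor SREBP-1, from 15.1 ± 0.890 to 25.4 ± 4.91 CPM (0.75, SE 0.15), and Agpat2, an acyltransferase gene, from 130 ± 8.63 to 187 ± 22.4 CPM (0.53, SE 0.12; SD, n = 4 each). Lpin1, which encodes a phosphatidate phosphatase that is also induced in fasting, went from 923 ± 223 to 292 ± 131 CPM (−1.66, SE 0.31). Over all genes tested by edgeR 0 members passed, with adjusted p values of 0.113, 0.109, 0.179 and 0.0990 for these 4, and 6 had an unadjusted p under 0.05; DESeq2 called 3 higher and 1 lower, limma-voom 0, and limma-voom with sample weights 3 higher and 1 lower. Fasn, the fatty acid synthase gene, was at 0.16 (SE 0.21, adjusted p = 0.836). The list as a whole was higher, with 17 positive members, a median of 0.14 and a camera adjusted p = 0.0202, and an adjusted p = 0.142 with an estimated correlation.

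Gluconeogenesis and fasting amino acid genes were lower as a group in Nudt7 livers, with 19 of 25 tested members negative and a median of −0.24 log2 units. In edgeR Igfbp1 fell over all genes tested, 4 members fell when adjusted over the list alone and 8 had an unadjusted p under 0.05; DESeq2 called 3 lower, limma-voom 1 and limma-voom with sample weights 2. Beside Igfbp1, those that fell when adjusted over the list alone were Got1, a cytosolic aspartate aminotransferase gene (−0.83, SE 0.21, 370 ± 74.5 against 657 ± 164 CPM), Tat, the tyrosine aminotransferase gene (−0.85, SE 0.21, 1556 ± 449 against 2800 ± 485 CPM), and Irs2, an insulin receptor substrate gene (−0.74, SE 0.22, 58.3 ± 20.1 against 97.3 ± 12.4 CPM; SD, n = 4 each). Their adjusted p values over all genes were 0.212, 0.225 and 0.370. Pck1, the rate-limiting enzyme gene of gluconeogenesis, was at −0.57 (SE 0.23, adjusted p = 0.528). Camera gave the list an adjusted p = 4.00e-05, and an adjusted p = 0.142 with an estimated correlation, or 0.0498 when Nudt7 replicate 3 was also left out, a fit chosen after the data were seen. The list shared 7 genes, Pck1, Cps1, Hal, Sds, Ass1, Asl and Arg1, with the list of periportal hepatocyte markers. Without these, in a test chosen after the data were seen, 12 of 18 members were negative, with a median of −0.21 and an adjusted p = 0.00175, or 0.270 with an estimated correlation.

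Circadian clock genes did not pass as a group (20 tested, 12 negative, median −0.09, camera adjusted p = 0.283, and adjusted p = 0.677 with an estimated correlation). Nfil3 was at −0.65 (SE 0.18, adjusted p = 0.289), Per1 at −0.59 (SE 0.19, adjusted p = 0.444), Nr1d1 at −0.09 (SE 0.33, adjusted p = 0.951) and Dbp at 0.32 (SE 0.26, adjusted p = 0.741). In edgeR 0 members passed over all genes or adjusted over the list alone, and 2 had an unadjusted p under 0.05; DESeq2 and limma-voom each called 0. Without GFP replicate 4 the list passed at adjusted p = 0.0301.

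**Figure D3:**
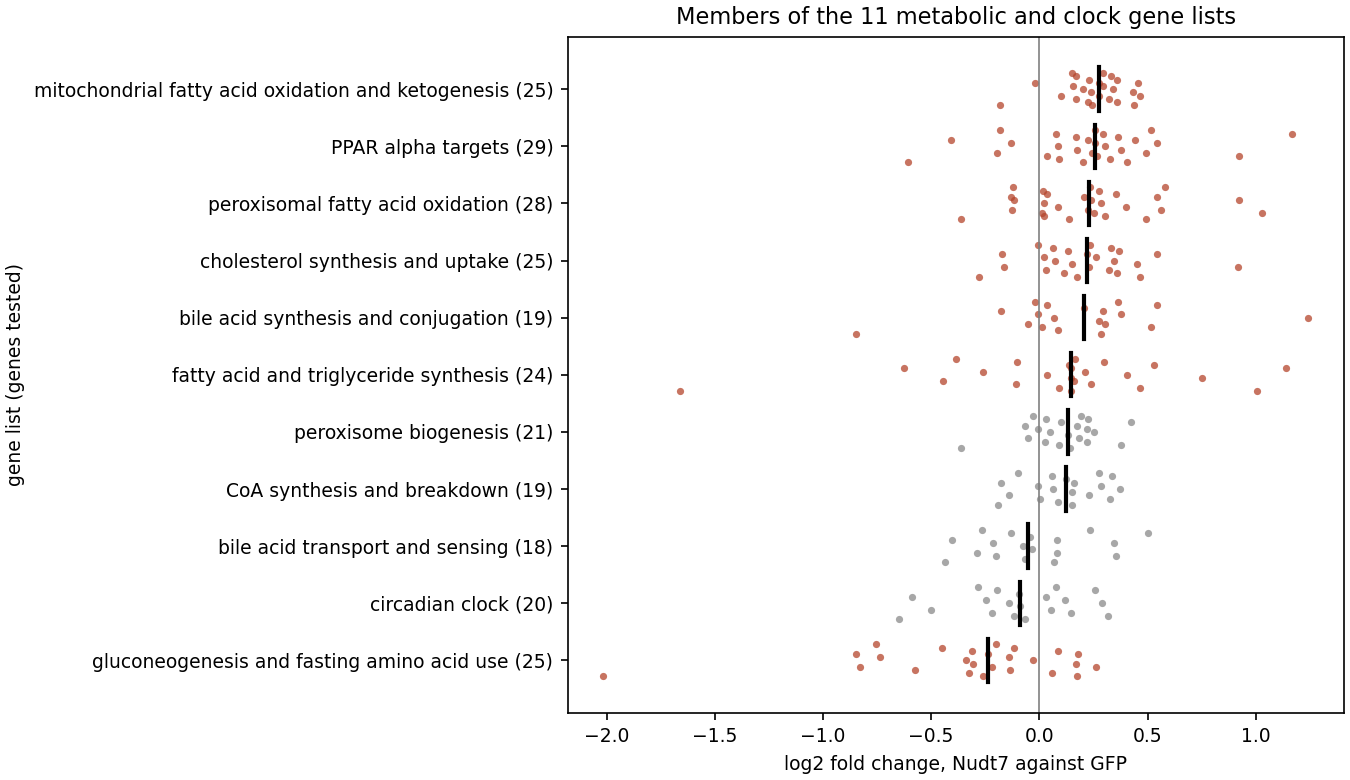
Log2 fold change of each tested member (points) of the 11 metabolic and clock gene lists, with the list median (black line) and the number of genes tested in brackets; red lists passed camera with a preset correlation and grey ones did not. Medians run from −0.24 for gluconeogenesis and fasting amino acid use to 0.27 for mitochondrial fatty acid oxidation and ketogenesis.

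With a preset correlation between genes, camera called 7 of the 11 metabolic and clock lists (Benjamini-Hochberg over 30 lists). With an estimated correlation it called 0 of the 30 lists, the smallest adjusted p being 0.142, while 8 lists had an unadjusted p under 0.05. Without 1 library it called 0 lists in 7 of 8 fits and gluconeogenesis without Nudt7 replicate 3 (adjusted p = 0.0498). The rotation test fry, which asks whether the members of a list move one way on balance, also called 0, with 9 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0662. Its test for change in either direction called 9 lists.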

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

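Tests chosen only after their result was seen were those of blood, of the length trend as the cause of the whole distance, of Nudt7 replicate 3 alone, of a milder fast, of periportal hepatocytes and of reads shared between Apol7 genes, and removal of the length trend, and an estimated correlation without Nudt7 replicate 3, were themselves added alternatives. A sample was singled out where its gap to the nearest of its group, divided by the group's range, exceeded Dixon's 95% critical value. That happened in 11 of the 170 groups of values examined, where chance gives about 1 in 20, and 8 of the 11 were in Nudt7 replicate 3.

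Nudt7 replicate 3 stood at 63.1 on the first principal component (other Nudt7 livers −8.14 to −2.88), had a rank correlation with its group of 0.966 (others 0.978 to 0.980) and held 3569 CPM of Nudt7 (others 1301 to 1599). Its deviation from the other Nudt7 libraries fell with transcript length across genes (Spearman rho −0.556, genes not being independent replicates). In the GFP libraries rho ran from −0.148 to 0.116. The other Nudt7 libraries (0.313 to 0.346) were measured against a mean that included replicate 3. A trend with transcript length may therefore account for part of the distance of replicate 3. It does not account for all of it, since removing the trend lowered the distance on the first component by 13.6%. More blood was argued against as the main source of its displaced reads. Red blood cell transcripts, though highest in that library (1813 CPM), gained 0.133% of its reads. In all, 18.4% of its reads were displaced from the mean of the other Nudt7 livers, so red cell transcripts made up 0.725% of the displaced reads. Their part in the distance on the first component, which was taken on log2 CPM, was not tested. Whether the highest Nudt7 level (3569 CPM, next 1599) underlies the remaining distance cannot be told apart from other properties of that liver, because it is a single liver.

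Within that library, the level of Mvk was 4.61 CPM (2.56 to 2.80 in the other Nudt7 livers). Nudt19 stood at 47.5 CPM (29.3 to 31.1). Cyp27a1 stood at 569 CPM (315 to 342). Gstm2 stood at 26.7 CPM (18.6 to 19.9). Hbb-bs, a hemoglobin gene, stood at 786 CPM (113 to 223). In other libraries, Tat stood at 3518 CPM in GFP replicate 2 (2502 to 2668 in the other GFP livers), Pdk4 at 229 CPM in Nudt7 replicate 2 (64.5 to 82.2) and Oat at 793 CPM in Nudt7 replicate 1 (840 to 843).

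By camera with a preset correlation, peroxisomal fatty acid oxidation genes were higher and gluconeogenesis genes lower in Nudt7 livers (adjusted p = 4.00e-05 for each), but neither list passed with an estimated correlation (0.142 for each). With the preset correlation both calls stayed without Nudt7 replicate 3 (larger camera adjusted p of the lists 7.33e-05) and with the trend with transcript length removed (larger 6.81e-05). Neither that library nor the trend was therefore needed for the calls at that setting. The setting also called lists in splits that joined 2 livers of each group, so a kept call cannot exclude either explanation. With an estimated correlation and the trend removed, the adjusted p was 0.130 for each list. Fewer periportal hepatocytes in the Nudt7 samples could be the source of the fall of the gluconeogenesis genes. The 9 periportal markers that are not on that list had a median of 0.14 log2 units (bootstrap SE over genes 0.12, with 6 higher and 3 lower). That lay above the median of the list (−0.24), which goes against such a loss as the whole source. The SE takes genes as units and holds no variation between livers, so the question stays open. With the 7 shared genes 10 of 16 periportal markers were lower (median −0.13). Of 16 pericentral markers 14 were higher (median 0.30, camera adjusted p = 0.000522, or 0.142 with an estimated correlation). The 7 shared genes are among those whose fall is in question, so their fall is no separate sign of a shift between zones. The pericentral values go with such a shift, and the 9 other periportal markers do not. A milder fast in the Nudt7 mice cannot be told apart from an effect of Nudt7, because 8 of 12 fasting-induced PPAR alpha targets were higher and 4 lower, with a median of 0.13 log2 units (bootstrap SE over genes 0.14). An effect of Nudt7 itself, the difference the design names, may underlie both lists and stays open, since with an estimated correlation the adjusted p was 0.170 for peroxisomal and 0.0498 for gluconeogenesis genes without Nudt7 replicate 3 (gluconeogenesis 0.217 to 0.342 without any 1 of the others).

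Apol7e was listed at 0 in every Nudt7 library, with 46, 87, 57 and 92 reads in GFP replicates 1 to 4. Assignment of its reads to near-identical Apol7 genes is a candidate explanation, as Apol7b and Apol7e summed had a log2 change of −0.32 (SE 0.20, adjusted p = 0.685), where a loss of Apol7e with Apol7b at its GFP level would give −1.18. Apol7b, which shares most of its words with other Apol7 genes, held 96, 94, 53 and 95 reads in Nudt7 replicates 1 to 4 and 57, 31, 37 and 117 in the GFP replicates. A true fall of Apol7e stays open, since reads assigned among copies do not show which copy was transcribed.

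Chance was tested by fitting all 35 splits of the 8 libraries into 4 and 4. Of the other splits, 16 joined 3 livers of one group with 1 of the other, and so kept part of the real contrast, and 18 joined 2 with 2. The real split called 16 genes and the highest other split 1, so 1 of 35 splits gave as many, the fewest possible. The counts were 15 and 1 without Nudt7, which the vector supplied. The splits argue against chance for the count of genes but cannot exclude it. Peroxisomal fatty acid oxidation (1 of 35 splits with a camera p as small as the real 7.37e-06, smallest other 8.81e-06) and bile acid synthesis (1 of 35, real 0.00756, smallest other 0.00793) had their smallest p in the real split. The next p was from a split of 3 and 1 and almost as small. A count of 1 of 35 is the smallest possible and was not adjusted over the 7 called lists, so chance cannot be excluded for either list. With an estimated correlation neither list passed (adjusted p = 0.142 and 0.456), and without Nudt7 replicate 3 bile acid synthesis had a camera adjusted p = 0.238. By the count of all splits, chance cannot be excluded for mitochondrial fatty acid oxidation (2 of 35, real 4.33e-08, smallest other 2.40e-11), PPAR alpha targets (6 of 35, real 1.49e-06, smallest other 1.08e-10), cholesterol synthesis (2 of 35, real 0.000542, smallest other 1.27e-05), fatty acid and triglyceride synthesis (2 of 35, real 0.00807, smallest other 0.000537) or gluconeogenesis (3 of 35, real 8.00e-06, smallest other 3.68e-07). The splits as small were all of 3 and 1, except 1 split of 2 and 2 for PPAR alpha targets (9.90e-09). Among splits of 2 and 2 the smallest p was 7.50e-06 for mitochondrial fatty acid oxidation, 0.00661 for cholesterol synthesis, 0.0490 for fatty acid and triglyceride synthesis and 0.00457 for gluconeogenesis. The real split called 12 lists, the splits of 3 and 1 up to 17 and the splits of 2 and 2 between 1 and 9, with a median of 5.5, so camera with a preset correlation also called lists where the groups were balanced. As many lists as in the real split were called in 4 of 35 splits, the real one included, so chance cannot be excluded for the number of lists.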

How the results depend on the processing

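Removal of the length trend, summing of the Apol7 genes, an estimated correlation with the length trend removed or Nudt7 replicate 3 left out, and the gluconeogenesis list without periportal markers were chosen after seeing the data; all other alternatives were planned. Nudt7 kept its direction and its call in all 8 fits without 1 library (log2 fold change 4.37 to 4.97) and in the 13 other alternatives (4.39 to 5.38). The 6 genes that rose became 15 with no filter on low counts, 89 with DESeq2, 57 with limma-voom and sample weights, 26 with the length trend removed and 12 at a threshold of 0.1, and 1 to 8 without 1 library. The 10 genes that fell became 6 with upper-quartile scaling, 64 with DESeq2, 4 with limma-voom, 46 with limma-voom and sample weights, 6 without robust estimation, 17 with the length trend removed and 5 with the Apol7 genes summed, and 1 to 12 without 1 library. At a threshold of 0.1 more genes pass by construction and with a library left out fewer samples remain; for the other changes the cause was not tested. Fewer genes rose without Nudt7 replicate 1 (1) or GFP replicates 1 (3), 2 (2) or 4 (1), and fewer fell without Nudt7 replicates 1 (1), 2 (5), 3 (5) or 4 (1) or GFP replicates 1 (2), 2 (1) or 4 (1). Removing the length trend kept 5 of the genes that rose, without Car3 (adjusted p = 0.0662), and all 10 that fell.

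Each of the 7 called lists lost its call with an estimated correlation and with fry. Adjusted p values were 0.142 and 0.0662 for peroxisomal fatty acid oxidation, cholesterol synthesis, fatty acid and triglyceride synthesis and gluconeogenesis, 0.2999 and 0.155 for mitochondrial fatty acid oxidation, 0.331 and 0.239 for PPAR alpha targets, and 0.456 and 0.334 for bile acid synthesis. Fry does not compare a list with other genes, and the cause of the other losses was not tested. For fatty acid and triglyceride synthesis the estimated correlation was −0.0081, below the preset 0.01, which argues against a higher correlation between genes as the cause for that list. With an estimated correlation and the length trend removed, adjusted p was 0.130 for peroxisomal fatty acid oxidation, cholesterol synthesis and gluconeogenesis, 0.132 for fatty acid and triglyceride synthesis, 0.302 for mitochondrial fatty acid oxidation, 0.333 for PPAR alpha targets and 0.387 for bile acid synthesis. With an estimated correlation and Nudt7 replicate 3 left out, gluconeogenesis kept its call (0.0498), while adjusted p was 0.170 for peroxisomal fatty acid oxidation, cholesterol synthesis and fatty acid and triglyceride synthesis, 0.268 for mitochondrial fatty acid oxidation, 0.447 for PPAR alpha targets and 0.446 for bile acid synthesis. Without the periportal markers gluconeogenesis kept its call (0.00175), but not with an estimated correlation (0.270). Without 1 library, adjusted p ran from 0.00826 to 0.238 for bile acid synthesis (0.238 without Nudt7 replicate 3), 0.0350 to 0.248 for CoA synthesis and breakdown (0.0350 without GFP replicate 4), 0.0150 to 0.852 for peroxisome biogenesis (0.0331, 0.0175 and 0.0150 without Nudt7 replicate 1, Nudt7 replicate 4 and GFP replicate 4) and 0.0301 to 0.689 for the clock (0.0301 without GFP replicate 4); the cause was not tested.

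Of 1657 values of named genes under the alternatives, 1493 kept their side of the threshold, 116 lost the call, 48 gained it and 0 changed sign with a call in either fit; 15 values without a call changed sign. For the context lists 280 of 322 values kept their side of the threshold, 20 lost the call and 22 gained it, 17 of these without 1 library (named under the other observations). DESeq2 called 25 named genes that edgeR did not, such as Acaa1b, Abcd3, Scd1, Lpin1 and Tat. Simulated 1.5-fold changes were recovered in 15.6% of cases at this depth and number of livers, and the part of depth in this was not tested. The simulations held 200 changed genes each and gave more calls than the real data. That loosens the adjusted threshold, so 15.6% may be too high for the real libraries.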

Other observations

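Tests chosen only after the result was seen were those with the length trend removed, of periportal markers without shared genes and of glucocorticoid-responsive genes adjusted over all lists. Among responses outside the main lists, NRF2 targets, antioxidant and detoxification genes, were higher as a group in Nudt7 livers (18 tested, 14 positive, median 0.41, camera adjusted p = 1.07e-05, and adjusted p = 0.142 with an estimated correlation). Of these, 6 rose when adjusted over the list alone, among them Gstm4 (0.97, SE 0.20), Cyp2a5 (1.24, SE 0.29) and Gstm2 (0.75, SE 0.17), and 0 over all genes in edgeR, while 8 had an unadjusted p under 0.05 and DESeq2 called 3, limma-voom 0 and limma-voom with sample weights 2. Male-biased liver genes were higher (18 tested, 16 positive, median 0.43, adjusted p = 6.21e-06, and adjusted p = 0.331 with an estimated correlation), with Cyp4a12b at 0.98 (SE 0.21, adjusted p = 0.132) and Mup21 at 0.97 (SE 0.26, adjusted p = 0.277). Female-biased genes did not pass (10 tested, median −0.12, adjusted p = 0.0866), although adjusted over the list alone Rtn4 rose (0.50, SE 0.11) and Fmo2 (−1.22, SE 0.27) and Cux2 (−0.85, SE 0.21) fell. Acyl-CoA thioesterases and synthetases were higher (25 tested, 20 positive, median 0.25, adjusted p = 0.000358, and adjusted p = 0.142 with an estimated correlation), with Slc27a1, a fatty acid transport protein gene, at 0.79 (SE 0.20). Several of these genes, such as Cyp4a12b, Mup21, Gstm2 and Gstm4, belong to families of similar copies, so their reads may be shared as those of Apol7e may be, where Apol7b and Apol7e summed had a log2 change of −0.32.

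Among liver cell types, markers of pericentral hepatocytes were higher as a group (16 tested, 14 positive, median 0.30, adjusted p = 0.000522, and adjusted p = 0.142 with an estimated correlation), with Oat at 0.44 (SE 0.14, adjusted p = 0.386) and Lect2 at 0.85 (SE 0.28, adjusted p = 0.444). Periportal markers did not pass (16 tested, median −0.13, adjusted p = 0.0866), with Etnppl at −0.61 (SE 0.18, adjusted p = 0.368), and the 9 that are not on the gluconeogenesis list had a median of 0.14 (adjusted p = 0.8002). Cholangiocyte markers were higher (7 tested, median 0.32, adjusted p = 0.000739, and adjusted p = 0.142 with an estimated correlation), with Spp1 at 1.13 (SE 0.22), which rose when adjusted over the list alone, and Epcam at 0.89 (SE 0.35, adjusted p = 0.526). Camera adjusted p values of the other lists were 0.3005 for Kupffer cells, 0.234 for endothelial cells, 0.723 for stellate cells, 0.727 for lymphocytes, 0.0866 for red blood cells (median 0.71, Hbb-bs 0.74, SE 0.52), 0.0866 for adipocytes and pancreas, and 0.727 for mitochondrially encoded transcripts. Red blood cell transcripts stood at 1813 CPM in Nudt7 replicate 3, 303 to 642 CPM in the other Nudt7 livers and 412 to 598 CPM in GFP livers. The groups overlapped both with and without that library. The interferon response (0.0844), xenobiotic cytochromes P450 (0.0700), acute phase response (0.283) and p53 targets and cell cycle (0.773) did not pass, nor did ER stress genes (0.487), whose median of 0.06 and mean of −0.05 differed in sign and whose test pointed down. Of the lists that did not pass, some passed without 1 library: without Nudt7 replicate 1 xenobiotic cytochromes P450 (0.0286) and ER stress (0.0219); without Nudt7 replicate 2 the interferon response (0.0492), cytochromes P450 (0.00369) and red blood cells (0.00126); without Nudt7 replicate 3 the acute phase response (0.0154), periportal markers (0.0210), mitochondrially encoded transcripts (0.0221) and adipocytes and pancreas (0.0291). Without Nudt7 replicate 4 female-biased genes (0.00580) and Kupffer cells (0.00207) passed; without GFP replicate 1 the interferon response (0.0207) and female-biased genes (0.0409); without GFP replicate 2 Kupffer cells (0.0472); without GFP replicate 3 cytochromes P450 (0.0131) and female-biased genes (0.0485); and without GFP replicate 4 cytochromes P450 (0.0300). With no filter on low counts cytochromes P450 (0.0322), periportal markers (0.0417) and red blood cells (0.0288) passed, as did the interferon response with a filter of 1 CPM in 4 samples (0.0490) and periportal markers with length-scaled TPM (0.0448). Neutrophil markers had 2 tested members and were not tested as a list.

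Fkbp5, Igfbp1, Tat and Per1, which glucocorticoids induce in liver, had negative fold changes in Nudt7 livers, past the threshold over all genes for Fkbp5 and Igfbp1 only, and lower glucocorticoid signalling is a candidate explanation. Without 1 library, Fkbp5 passed in 0 of 8 fits (adjusted p 0.0578 to 0.188) and Igfbp1 in 1 of 8 (0.0143 to 0.162). That explanation was tested on 20 other glucocorticoid-responsive genes chosen before their values were seen, of which 19 were measured. Of these 18 were lower and 1 higher, with a median log2 change of −0.35, and camera with an estimated correlation gave p = 0.00527. That p is for this list alone, as planned for it; adjusted together with the 30 other lists it was 0.0998, which did not pass. Ddit4 was at −2.07 (SE 0.46, adjusted p = 0.179), Zbtb16 at −0.98 (SE 0.23, adjusted p = 0.175), Hif3a at −0.91 (SE 0.25, adjusted p = 0.281) and Tgm2 at 0.44 (SE 0.16, adjusted p = 0.490); in edgeR 0 of the 19 passed over all genes, 8 had an unadjusted p under 0.05, and of the 4 named DESeq2 called Ddit4 and Zbtb16. The p stayed between 0.00669 and 0.0217 in all 8 fits without 1 library (median −0.39 to −0.25) and was 0.0245 with the length trend removed (median −0.31). Of the 35 splits of the libraries, 1 gave a p as small, the smallest other being 0.0531, and 1 is the smallest count possible. The explanation was raised from Fkbp5, Igfbp1, Tat and Per1 in these same livers. Genes that share a regulator may vary together between livers, so neither the p nor the count of splits can exclude chance. Several of the glucocorticoid-responsive genes also respond to fasting or insulin, which was not tested apart, and corticosterone was not measured, so the explanation remains a hypothesis.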
